A study of Mus musculus with 4 samples.

How the data were processed

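Trimethylation of lysine 9 on histone H3 (H3K9me3), a mark of silent chromatin laid down in part by the histone methyltransferase SUV39H1, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq). The cells were mouse CD8+ T cells on a C57BL/6 background, kept for 3 days in culture with antibodies to CD3 and CD28 and with interleukin-2. Per the labels, 4 libraries were made, 1 H3K9me3 library and 1 input library for each of 2 genotypes, wild type (WT) and Suv39h1 knockout (KO). The 2 H3K9me3 libraries were analysed through 1 deposited list of islands each, and the inputs are not analysed here. Groups were taken from the genotype and antibody labels.

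The submitters' processing notes name Bowtie2, SICER 1.1 and the mm10 genome build. The window size, gap size, threshold on the false discovery rate, duplicate handling, read filters and the use of the input in calling are not given in the sources used here. The deposited coordinates lie on a grid of 500 bp, with the start counted from 0 and the end being the last base of the last window, also counted from 0. They were converted to positions counted from 1. The lists were made separately for each library. The smallest gap between islands in both lists is 2000 bp. The deposited lists also hold a whole-number count per island, for which the files have no header. It was read as the count of ChIP reads in the island, since it follows island length (Spearman rho across islands 0.973 in WT and 0.980 in KO). The authors' counts carry no scaling to library depth or input, per their values, and whole-library depth is not known here. Counts were used to describe and filter islands within a list, and are given per kb beside the covered length. Reads per kb were also compared between the lists, without scaling, over islands called at nearly the same place in both.

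Genes came from a RefSeq table of assembly GRCm38.p6, the assembly that mm10 names. Its 348 nuclear genes on scaffolds outside the chromosome sequences, recognised by the order of the table, were left out, a step taken after the data were seen. The pool held 21774 protein-coding genes and 374 variable segments of antigen receptor genes. The planned region of a gene was its body with 2 kb upstream. Gene strand was not used here, so the region became the gene with 2 kb on each side. For the same reason windows around gene starts were not run. Exons, introns and genome sequence were not used here, so location is given as inside or outside annotated genes, the repeat and GC content of islands was not computed, and random placement could not leave out assembly gaps.

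An island counted as overlapped when at least 1 bp was covered by an island of the other list. Overlap was set beside 200 shuffles that placed the WT islands at random between the first and last island of each chromosome, and beside 200 local shifts of each WT island by up to 500 kb. Gene counts and location were set beside 100 shuffles. Shares of islands have exact (Clopper-Pearson) 95% binomial intervals, which cover counting of islands only. A gene counted as having an island when at least 1 bp of its region was covered. The 24 gene lists were fixed before the data were examined, 10 by symbol and 14 by name pattern, and 219 of the 223 symbols matched the table. They cover stem-like and memory, effector, inhibitory, T cell identity and other T lineage genes, other blood cells, H3K9 methylation machinery, germline, imprinted and housekeeping genes. By pattern they cover Hox, zinc finger, olfactory and vomeronasal receptor, clustered protocadherin, killer lectin-like receptor, MHC, keratin, cytochrome P450, serpin, defensin, immunoglobulin and T cell receptor variable segment and histone genes. Each list's share of members with an island was placed among 10000 random lists of the same size, matched on region length in 20 bins. Random lists take genes singly, whereas neighbouring members of a clustered family share islands, so percentiles of such families are more extreme than independent genes would give.

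Genes are named by a rule fixed before the data were examined. In the 5 T cell lists, it took up to 6 members per list and genotype with an island in that genotype alone, and up to 2 covered in both with the largest difference in length. It added the 6 protein-coding genes with the longest cover in each genotype alone, leaving out clone-type symbols, and Suv39h1, Suv39h2, Setdb1 and Trim28. From every other list it took up to 2 members per genotype with the longest cover. The 3 longest islands and the 3 longest stretches covered in 1 genotype alone completed it. Names outside this rule are marked as chosen after their values were seen.

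With 1 library per genotype, no test between genotypes was made and no p-value is given. Values describe these 2 libraries, and random placements and random lists describe chance within them. Other settings fixed beforehand were islands above the median of reads per kb, a KO list reduced to the WT number by reads, merging of islands under 5 kb apart, islands of at least 2 kb, autosomes alone, stricter overlap and stricter cover of genes. The reduced KO list drops KO islands alone, so KO minus WT in a gene list or gene can only fall or stay there. Chosen after the data were examined were the gene without flanks or with 10 kb on each side, lists without the 1% of islands with most reads per kb, and local shifts. So were the bins of 1 Mb with their gene number classes, classes by gene length or reads per kb, pairs of islands with 80% reciprocal overlap, those of them at 1.5 times the median of reads per kb or more, the pooled T cell lists, 2000 random lists matched also on the number of genes within 500 kb, and random lists drawn outside the list and outside olfactory and vomeronasal receptor genes, which fill much of the shortest length bins.

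Overlap and list code was tested on simulated data. Overlap of the 12371 WT islands with a simulated KO list was recovered within 0.00404 percentage points. Of 20 simulated lists of 26 genes of which 13 were given KO islands, 20 lay above percentile 97.5, as did 0 of 20 lists without them, among 22148 genes. These are checks of the code. They do not show that differences as small as those in the T cell lists would be found. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.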

Results

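H3K9me3 was compared between cultured CD8+ T cells of WT mice and of mice lacking Suv39h1, with 1 H3K9me3 library per genotype. The question was where the mark lies in activated CD8+ T cells with and without this methyltransferase, and whether genes of T cell differentiation lie under it. The WT list held 12371 islands with 5547695 reads, and the KO list held 25424 islands with 10020253 reads. There were no replicates, so values are set side by side without a test. A gene listed in 1 genotype alone had no called island in the other, which does not exclude the mark there.

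More of the genome lay in called H3K9me3 islands in the KO library than in the WT library. Islands covered 136 Mb in WT and 249 Mb in KO, a ratio of 1.83, and their number differed by 2.06 times. Over the autosomes this was 5.70% in WT and 10.4% in KO. KO cover was higher on 19 of 19 autosomes, by 1.24 to 2.59 times. Single islands were alike in both lists, with a mean length of 11 kb in WT and 9.80 kb in KO and a median of 40.4 and 40.1 reads per kb. In both lists most islands lay little above the lowest densities called. The 1st percentile was 34.3 in WT and 34.1 in KO, and the upper quartile 43 and 42.6. Like medians therefore do not show equal enrichment.

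The added KO cover lay where genes are few. In autosomal 1 Mb bins without protein-coding genes, islands covered 5.92% of the sequence in WT and 18.6% in KO, a ratio of 3.14. In bins with 1 to 4 genes the values were 6.48% and 14.6%, and in bins with 5 to 12 genes 5.69% and 7.16%. In bins with 13 or more genes they were 4.27% and 4.70%, a ratio of 1.1. Across 2387 bins, cover in WT and KO correlated with Pearson r 0.523 and Spearman rho 0.544, and the rho between cover and gene number was -0.17 in WT and -0.56 in KO. Neighbouring bins are not independent. Protein-coding genes held 32.4% of island length in WT and 26.9% in KO, against means of 41.3% and 41.0% in shuffled lists.

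**Figure D1:**
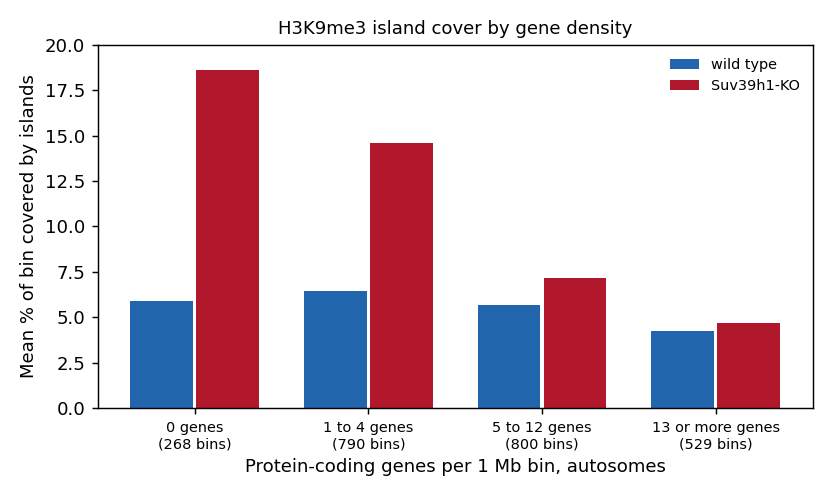
Mean percent of 1 Mb autosomal bins covered by H3K9me3 islands (y axis) by the number of protein-coding genes in the bin (x axis), for WT (blue bars) and Suv39h1-KO (red bars), 1 library each. The KO bar stands at 18.6% against 5.92% in WT in bins without genes and at 4.70% against 4.27% in bins with 13 or more.

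Most islands of either list had no partner in the other. Of the WT islands, 5939 (48.0%, 95% interval 47.1 to 48.9) were overlapped by a KO island, and of the KO islands 6321 (24.9%, 24.3 to 25.4) by a WT island. Shuffled WT islands gave means of 20% and 10.5%, and WT islands shifted locally gave 27.9% and 13.6%. Both lists shared 43.7 Mb, while 92.6 Mb was in WT alone and 205 Mb in KO alone, a Jaccard index of 0.128. Of the KO islands, 14.7% were overlapped in the 10% with fewest reads per kb and 34.3% in the 10% with most. In WT these shares were 44.8% and 51.3%. Relative to local shifts, which take account of the shorter length of dense islands, the ratio of the higher to the lower share was 2.06 in KO and 2.30 in WT, a correction chosen after the plain shares were seen. The overlap was 32.5% of WT and 16.3% of KO islands among those above the median of reads per kb, and 29.4% and 29.2% with equal numbers of islands, where the KO islands with most reads, largely the longer ones, were kept.

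**Figure D2:**
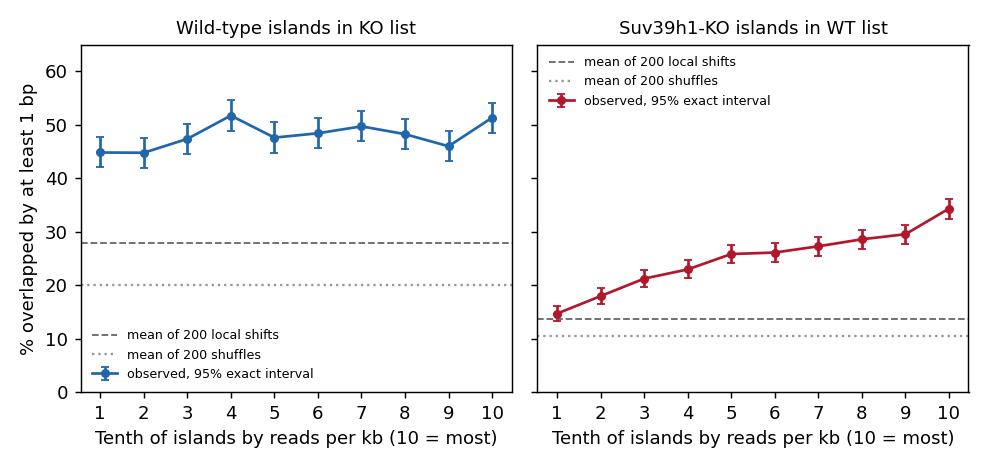
Percent of islands overlapped by the other genotype's list (y axis) in 10 equal groups of islands ordered by reads per kb (x axis), for WT islands (left) and Suv39h1-KO islands (right), with exact 95% intervals of the counts. Dashed and dotted lines are the means of 200 local shifts and 200 shuffles of all WT islands. KO shares go from 14.7% in the lowest group to 34.3% in the highest, and WT shares lie between 44.8% and 51.7%, without correction for the shorter length of dense islands (ratios of highest to lowest group with it are 2.06 in KO and 2.30 in WT).

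Protein-coding genes with an island were about as many in the 2 genotypes. Of 21774 genes, 3043 had an island in WT and 2993 in KO, of which 1651 had one in both, 1392 in WT alone and 1342 in KO alone. Shuffled lists gave means of 4736 genes in WT and 7736 in KO. By the length of the gene region, which includes the 2 kb on each side, regions of 10 to 30 kb had islands in 572 cases in WT and 437 in KO, and those of 30 to 100 kb in 878 and 697. Regions under 10 kb had them in 488 and 757 cases. Olfactory and vomeronasal receptor genes, described below, fill much of the shortest length bins, so this count partly reflects those families. Among regions of 100 kb or more the numbers were 1105 and 1102, with 32.3 Mb covered in WT and 58.1 Mb in KO. The split between WT and KO alone became 1945 and 731 genes with equal numbers of islands. Only KO islands are dropped in that setting, so genes in KO alone could only fall and those in WT alone only rise. The split became 382 and 519 when at least 50% of a gene region had to be covered.

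Ranking by covered length favours long genes in both genotypes. In KO alone, Ptprt, a receptor tyrosine phosphatase (chr2:161521988-162661147, mm10), carried 22 KO islands over 260.5 kb and no WT island. Cdh13, which encodes T-cadherin, carried 226 kb and Csmd2 182 kb. Mecom, a zinc finger transcription factor of blood stem cells, carried 161 kb, Skint5, of a family linked to the selection of skin gamma-delta T cells, 156 kb, and the glutamate receptor gene Grm7 148 kb. The longest cover in WT alone was over Samd12 (chr15:53399113-53902535), with 7 islands and 68 kb. Dnm3, a dynamin gene, carried 50.5 kb, the proteoglycan gene Vcan 50 kb, and Itga1, the collagen-binding integrin chain CD49a found on resident memory T cells, 48.5 kb. Zswim5 carried 45.1 kb and Dzip3, a ubiquitin ligase gene, 45 kb. Of the H3K9 methylation genes Suv39h1, Suv39h2, Setdb1 and Trim28, none had an island in either library. Suv39h1 lies on chromosome X, where only 2 islands were called in WT and 9 in KO, so its lack of an island says little. An island list does not show whether Suv39h1 itself was lost.

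In the 5 T cell lists, 7 of 111 genes had an island in WT alone and 0 in KO alone. Over all 21774 protein-coding genes, 6.39% had one in WT alone and 6.16% in KO alone. The count in WT alone was thus close to the share over all genes, and the count in KO alone was below it. The 7 genes included Il7r, the interleukin-7 receptor chain of naive and memory T cells. Il2rb, the shared interleukin-2 and interleukin-15 receptor chain, was another, as was Prdm1, the effector regulator BLIMP-1. Entpd1 (CD39) and Btla, both inhibitory, and Rora and Il1r1, genes used by other T lineages, completed the 7. A further 5 had islands in both, and 99 in neither, among them all 20 T cell identity genes.

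Il7r had the widest WT cover of these. A WT island at chr15:9503001-9522000 held 753 reads and covered 17.8 kb of its region, across 1 end of the gene. The nearest KO island in the window drawn lay outside the region, at chr15:9543001-9547000. The WT islands over Rora (13.5 kb in 2 islands), Entpd1 (9.50 kb), Btla (9 kb), Il1r1 (8.50 kb), Il2rb (7 kb, chr15:78499501-78506500) and Prdm1 (6.50 kb, chr10:44519501-44526000) lay inside the genes. Tox, a regulator of exhaustion, had 14.6 kb in 3 WT islands and 6 kb in 1 KO island, none of which overlapped. Overlapping islands of both genotypes lay over Bach2 (12 and 10.5 kb), Il23r (8 and 7 kb) and Il17a (7.59 and 5.60 kb). Zeb1 had 17.5 kb in WT and 14 kb in KO, and was longer in KO by 6.50 kb among islands above the median of reads per kb.

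**Figure D3:**
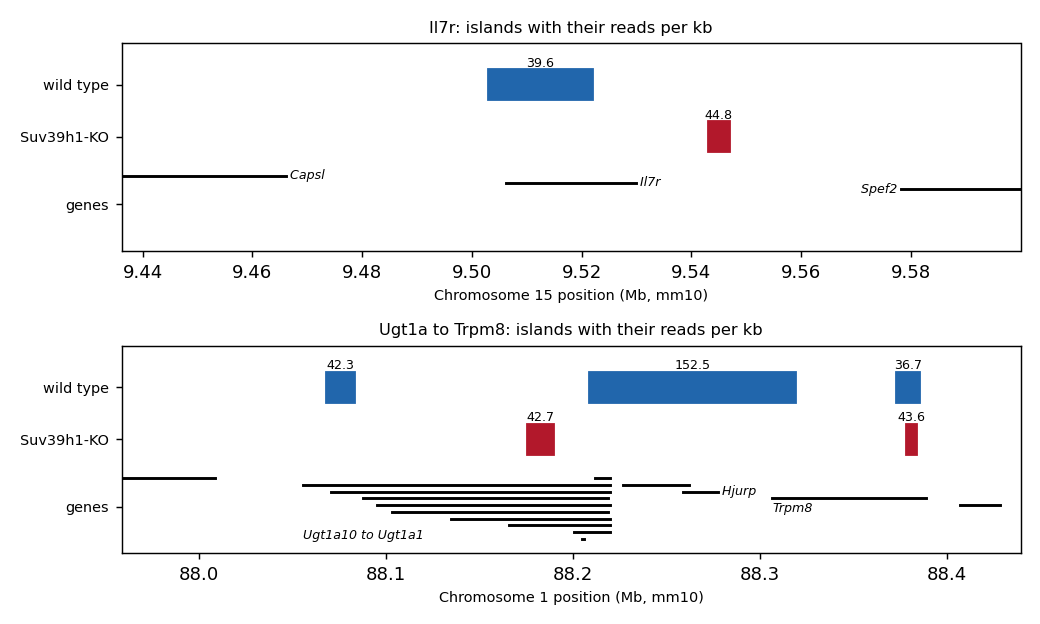
H3K9me3 islands of WT (blue) and Suv39h1-KO (red) with their reads per kb, above the protein-coding genes (black lines), along chromosome 15 around Il7r (top) and chromosome 1 from the Ugt1a cluster to Trpm8 (bottom), positions in Mb of mm10. A WT island covers much of Il7r with no KO island over it, and the WT island over Hjurp holds 152 reads per kb, with the input there not analysed.

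No single T cell list stood apart from random lists in its difference between genotypes. For stem-like and memory genes 4 of 26 had an island in WT and 2 in KO, and the difference lay at percentile 13.9 of length-matched random lists. The effector list had 1 and 0 of 29 genes (percentile 34.7), the inhibitory list 3 and 1 of 16 (11.9), T cell identity 0 and 0 of 20 (59.4) and other T lineages 4 and 2 of 20 (11.6). In level, T cell identity lay at percentile 1.13 in WT and 1.85 in KO, and the effector list at 8.96 in WT and 2.17 in KO, or 0.54 in KO with 10 kb on each side. With the 5 lists pooled, a step chosen after the data were seen, 12 genes had an island in WT (percentile 17.3) and 5 in KO (percentile 0.18). The pooled difference lay at percentile 7.13, and at 5.43 when random lists were matched also on gene density. With 10 kb on each side of the genes, 15 had an island in WT alone and 1 in KO alone, and the pooled difference lay at percentile 0.235. Among islands above the median of reads per kb, 4 genes had one in WT alone. With all islands and 2 kb on each side, the KO minus WT difference in points was -7.69 for stem-like and memory, -3.45 for effector, -12.5 for inhibitory, 0 for identity and -10 for other T lineage genes. Above the median of reads per kb it was -3.85 for stem-like and memory and 0 for inhibitory genes. With equal numbers of islands, where only KO islands are dropped and the difference cannot rise, it was -18.8 for inhibitory and -20 for other T lineage genes. With 10 kb on each side the 5 values were -11.5, -10.3, -18.8, -10 and -15 in the same order of lists.

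Chemosensory receptor genes carried islands more often in KO than in WT. Of 1108 olfactory receptor genes, 291 (26.3%) had an island in WT and 520 (46.9%) in KO, including Olfr183 with 22 kb in WT and 27.6 kb in KO. Random lists matched on region length had medians of 16.8% and 30.2%, and those matched also on gene density a median difference of 13.8 points. Of the 1069 genes in the length bin with most olfactory receptors, however, 858 are olfactory or vomeronasal receptor genes, so these lists are largely drawn from the families themselves. Drawn outside both families and outside the list, which was chosen after the data were seen, random lists had medians of 5.60% and 10.3%. With equal numbers of islands the olfactory difference was 4.69 percentage points rather than 20.7 (13.1 above the median of reads per kb), and Olfr183 reversed, with 9.38 kb more in WT. Vomeronasal receptor genes had 84 and 128 of 350, a difference that reversed to 1.71 points in favour of WT with equal numbers of islands. That setting drops only KO islands, so it can only lower KO minus WT or leave it. Of 99 cytochrome P450 genes, which encode steroid and drug oxidases, 18 had an island in WT and 33 in KO. Cyp2c39 had 50 kb in KO alone, while Cyp3a13 had 36.7 kb in WT and 6.50 kb in KO. The P450 difference of 15.2 points was 6.06 with equal numbers of islands and 5.05 above the median of reads per kb. With all islands, each of these 3 families lay at percentile 100 of random lists in its KO minus WT difference.

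Zinc finger genes went the other way. Islands covered 120 of 423 in WT and 95 in KO, a difference at percentile 0.20 of random lists, with shares of 28.4% and 22.5% that were both above the random ranges. The zinc finger difference was -5.91 points with all islands and -14.9 with equal numbers. The larger gap adds no support, since dropping KO islands alone cannot raise the KO share. Zfp982 (60.1 kb in WT, 58.1 kb in KO) and Zfp936 (58.1 and 55.1 kb) had like cover in both, though Zfp982 was longer in KO by 5 kb after merging of nearby islands and by 3.50 kb with wider flanks. The 2 neuronal genes Zfp804b (17 and 113 kb) and Zfp804a (12 and 91.4 kb) had more in KO. Clustered protocadherins, adhesion genes of neurons, had islands in 44 and 45 of 57 genes, but the KO share was lower by 29.8 points with equal numbers of islands and by 31.6 points above the median of reads per kb, and higher by 14 points without flanks.

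Variable segments of the T cell receptor had islands in 6 of 148 in WT and 2 in KO (difference at percentile 0.07, or 0.55 with random lists drawn outside the list and the chemosensory families), a gap of 2.70 points. The gap was 0.676 above the median of reads per kb or without flanks, 4.05 with equal numbers of islands and 6.08 with 10 kb on each side. Those of immunoglobulin genes had islands in 15 and 34 of 225. That difference lay at percentile 79.9 of length-matched random lists, and at 23.2 when they were drawn from autosomes. It lay at 99.9 when they were drawn outside the list and the chemosensory families, and at 100 when matched also on gene density. By that density count these segments had a median of 0 genes within 500 kb, against 16 over all genes. The density match therefore set them beside genes in gene-poor places. The immunoglobulin difference of 8.44 points was 0.889 with equal numbers of islands, 2.67 without flanks and 4.44 above the median of reads per kb. Genes of other blood cells had islands in 6 and 3 of 25, a difference at percentile 4.04, lower than that of any single T cell list. It was -12 points with all islands, -24 with equal numbers and 0 above the median of reads per kb. In this list the B cell adaptor gene Blnk was covered over 13.5 kb in WT alone and the macrophage gene Adgre1 over 16.5 and 11.5 kb. Of 22 H3K9 methylation genes 3 had islands in WT and 4 in KO, which became 9.09 points lower in KO with equal numbers of islands. Tasor, a subunit of the HUSH silencing complex, had 7.50 kb in WT alone, and the demethylase gene Kdm4c 9.50 kb in KO alone. No histone gene (of 70) and no housekeeping gene (of 20) had an island in either library.

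**Figure D4:**
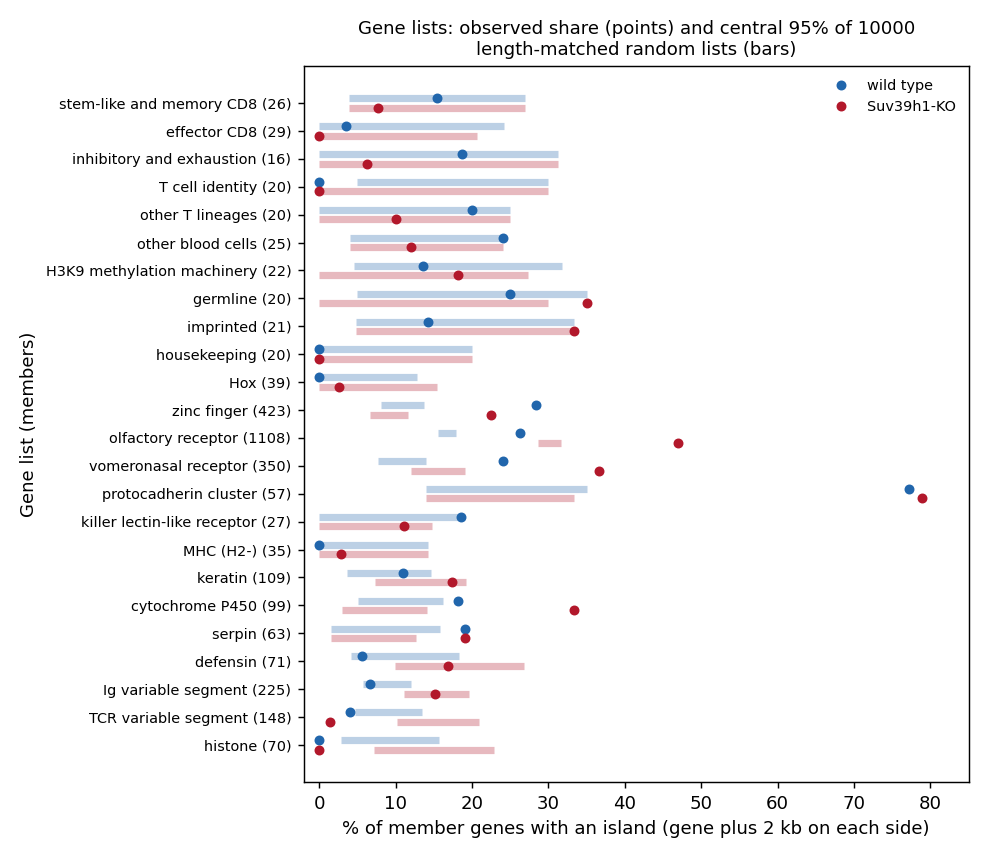
Percent of the genes of each fixed list with an H3K9me3 island (x axis) in WT (blue points) and Suv39h1-KO (red points), 1 library each, with list size in parentheses. Pale bars are the central 95% of 10000 random lists matched on region length. Olfactory receptors stand at 26.3% in WT and 46.9% in KO, vomeronasal receptors at 24% and 36.6% (the latter order flips with equal numbers of islands), and zinc finger genes at 28.4% and 22.5%.

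The longest islands of the 2 lists met at 1 locus. A WT island at chr3:106113001-106266000 spanned the chitinase-like genes Chia1, Chil3 and Chil4 over 153 kb with 11249 reads, and 3 KO islands covered 91.5% of it. The longest KO island, chr3:106186001-106266500, lay at the same place. The next WT island in length was chr1:88208501-88319500, over the ends of the Ugt1a cluster, Mroh2a, Hjurp and part of Trpm8. It held 16925 reads, or 152 per kb, and no KO island overlapped it. That density was 1.86 times the highest of the 88 other WT islands of 30 kb or more. The WT input over this stretch was not analysed here, so a higher copy number or input signal there was not checked. Further long stretches in WT alone lay at chr16:49087001-49128000 in Myh15 and chr14:119036001-119076500 in Uggt2. Those in KO alone lay at chr4:121995001-122047000, chr1:96280001-96325500 and chr10:107562501-107608000, the last at Ptprq. Other long islands were chr13:12881001-12942500 in WT, 95.9% covered in KO, and chr3:158250501-158330000 in KO, inside Lrrc7.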

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

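The value here was picked out after the data were seen, and no test was run on it. The KO list held 2 islands on the mitochondrial genome with 17486 reads, 0.175% of the reads in KO islands, and the WT list held none. Mitochondrial DNA carries no histones. Both islands and their reads are part of the KO totals of 25424 islands and 10020253 reads, and leaving out everything but autosomes gave 25409 KO islands.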

How the results depend on the processing

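Flanks of 0 or 10 kb, lists without the densest 1% of islands, and all settings applied to T cell genes and to gene lists (autosomes aside, for lists) were chosen after the data were seen. Windows around gene starts and repeat or GC content of stretches were not run. No paired analysis was possible because each genotype has 1 library. Island number, covered length, overlap and gene counts stayed within 1.5 times or their intervals on autosomes alone, with islands of at least 2 kb and without the densest 1%. KO cover exceeded WT cover in all settings run. KO island number did so in all but the reduced KO list, where it is equal by construction. In that setting KO cover was 163 Mb against 136 Mb in WT, from the KO islands with most reads, largely the longer ones. Whole-library depth is unknown, so how far depth limits the calls cannot be stated.

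Above the median of reads per kb, there were 6166 WT islands (57.4 Mb, 32.5% overlapped), 12707 KO islands (104 Mb, 16.3% overlapped) and 4 T cell genes in WT alone, which follows from leaving out the other islands. With the KO list reduced to 12371 islands by reads, KO cover was 163 Mb, overlap 29.4% of WT and 29.2% of KO islands, and genes in KO alone numbered 731. Merging islands under 5 kb apart gave 25.9% of KO islands overlapped. Overlap of at least 50% of the island gave 33.9% and 18.4%. Cover of at least 50% of the gene region gave 382 genes in WT alone, 519 in KO alone and 1 T cell gene in WT alone. With 10 kb on each side, 15 T cell genes were in WT alone and 1 in KO alone.

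Of 648 values for 81 named genes 18 reversed, and of 192 for 24 lists 7 did. The cause was not tested beyond the settings' own construction. The reduced KO list loses KO islands alone, so a reversal there can only go towards WT. KO minus WT above the median of reads per kb was -31.6 points for protocadherins and 3.70 for killer lectin-like receptors. In kb it was 6.50 for Zeb1, 6 for Ebf1, 4 for Vmn2r90, -19.7 for Vmn2r80, -17.3 for Pcdha1 and also -17.3 for Pcdha2, 13.5 for Klra2 and 5.08 for Serpini2. With the reduced KO list it was -9.09 points for H3K9 methylation genes, -5 for germline genes, -1.71 for vomeronasal receptors, -29.8 for protocadherins and -2.75 for keratins. In kb it was -11 for Atf7ip, -9.38 for Olfr183, -0.50 for Olfr872, -1.75 for Vmn2r80, -6.34 for Pcdha1, -2.13 for Pcdha2 and -3.93 for Klrh1. Merging gave 7.50 kb for Sycp1 and 5 kb for Zfp982, and 10 kb flanks 3.50 kb for Zfp982.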

Other observations

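The megabase bins, the densest islands, the chromosome X values and every test of an explanation in this part were chosen after the result was seen, whereas the gene lists were fixed before.

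Imprinted genes had islands in 3 of 21 members in WT and 7 in KO, a difference at percentile 98.6 of length-matched random lists. It was 19.05 points with all islands and 4.76 with equal numbers. The 4 members with KO islands alone are 2 pairs of neighbours, Peg3 with Usp29 and Peg10 with Sgce, so random lists of single genes overstate the percentile. Peg3, Peg10 and Sgce are named after their values were seen. Snrpn, of the imprinted region on chromosome 7, had 15.0 kb in WT and 117 kb in KO, and Usp29 had 66.7 kb in KO alone. Kcnq1 (52.5 and 45.0 kb) and Grb10 (21.0 and 13.5 kb) had more in WT. Germline genes had islands in 5 and 7 of 20, an order that reversed by 5 points with equal numbers of islands and was 15 points above the median of reads per kb, and the meiotic genes Sycp1 (65.5 and 64.5 kb) and Stk31 (46.0 and 32.0 kb) were covered in both.

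Serpin genes had islands in 12 of 63 members in each genotype, with -9.52 points in KO against WT at equal numbers of islands. Keratin genes had them in 12 and 19 of 109, a difference of 6.42 points at percentile 70.7 of random lists, or 97.485 when these were drawn outside the list and the chemosensory families. Random lists matched also on gene density had a median difference of 8.26 points and put it at percentile 29.1. The keratin difference reversed by 2.75 points with equal numbers of islands, and was 12.8 points at percentile 98.8 with 10 kb on each side. Defensin genes had them in 4 and 12 of 71 (11.3 points, 4.23 with equal numbers and 7.04 without flanks), a difference at percentile 81.9 of random lists, whose medians were 11.3% in WT and 18.3% in KO. Drawn outside the list and the chemosensory families, random lists had medians of 4.23% and 7.04% and put the difference at percentile 98.95. Killer lectin-like receptors had them in 5 and 3 of 27 (-7.41 points, 3.70 above the median of reads per kb and -18.5 with equal numbers), MHC genes in 0 and 1 of 35 and Hox genes in 0 and 1 of 39.

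Among 1 Mb bins, the largest excess of KO cover was at chr10:114000001-115000000, around Trhde, with 2.15% in WT and 42.2% in KO. The largest excess of WT cover was at chr13:19000001-20000000, with 20.4% and 5.35%. That bin holds Amph, Gpr141 and the T cell receptor variable segment Trgv1 among others, and copy number there was not checked. Trgv1 itself went the other way, with 0.454 kb of its flank covered in KO alone. The next largest excess of WT cover was at chr16:52000001-53000000, at 27.1% and 12.8%. It holds Alcam and Cblb, a ubiquitin ligase gene that restrains T cell activation. The islands with most reads per kb included chr11:3184001-3200500 in Sfi1 in both genotypes (787 and 798 reads per kb). An island at chr17:39832001-39849000, which holds the ribosomal RNA gene Rn18s-rs5, was listed in KO alone with 427 reads per kb. Input signal and copy number at Sfi1 and Rn18s-rs5 were not checked, so these densities need not reflect strong H3K9me3.

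More islands were listed in KO than in WT. A uniformly deeper KO library would raise reads per kb in islands at the same place, by 0.85 on the log2 scale if deeper by the ratio of island reads, but over 816 such pairs the median log2 ratio was -0.017 (quartiles -0.09 and 0.06), and over the 37 of them with a mean of at least 60.3 reads per kb, above the calling floor, it was 0.014 (highest 0.32). If calls were free of chance misses, a looser threshold in KO alone would leave nearly all WT islands overlapped, and 48.0% were. Chance misses near the threshold would lower this share too, so it cannot decide the question. The paired values argue against a uniformly deeper KO library as the whole cause, though the pairs hold only places called in both lists. The 1st percentiles of reads per kb were alike, at 34.3 in WT and 34.1 in KO. The lowest values were lower in KO, with 29.6 against 31.7 reads per kb and 56 against 65 reads per island. Median reads per island were 347 in KO and 405 in WT. The floor of reads per kb was thus alike except for the sparsest islands, and somewhat looser calling in KO is not excluded. A threshold looser relative to library depth cannot be excluded either, since depth is unknown. Enrichment efficiency, input, GC or replication-linked coverage, and the loss of Suv39h1 itself remain open, since each genotype has 1 library.

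Of the WT islands 6432, and of the KO islands 19103, had no overlap in the other list. If chance around the calling threshold were the source, dense islands would be shared more often, and the 10% with most reads per kb were overlapped 1.15 times as often as the 10% with fewest in WT and 2.33 times in KO, a mixed result against a bound of 1.5 in both. After that result was seen, each share was divided by its value under local shifts, because dense WT islands are short (median 5.5 kb against 13 kb), which gave 2.30 in WT and 2.06 in KO. Islands near the threshold may account for part of the lists' difference, but a real difference that spares strong islands would give the same ratios. The 2 therefore cannot be told apart here.

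Chromosome X held 2 islands in WT and 9 in KO, against 863 and 1773 expected from autosomal numbers by length. All of them lay within chrX:31224501-31781000 or chrX:169973001-170737000. The sex of the mice is not given in the sources used here. Chromosome Y held 1 island in WT and 4 in KO, with chrY:258501-259500 in both lists, and whether these come from male cells was not tested. If the cells were male, with 1 X copy each, reads per kb would be at 50% of the autosomal level, and islands that stay above the 1st percentile of reads per kb at that level would number 3.28 in WT and 4.19 in KO. The exact 95% Poisson intervals of the observed numbers are 0.242 to 7.22 and 4.12 to 17.1. Both expected numbers lie inside, in KO narrowly. With the lowest islands as the floor the expected numbers are 5.16 and 9.07. The intervals treat islands as independent and as lying on 1 copy in male cells, which was not checked for these clustered places. Every observed X island lay in them, so the comparison cannot decide the question. With that limit, a calling threshold shared by all chromosomes is a candidate explanation only for male cells, and no biological explanation was tested.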
